A study of Drosophila melanogaster with 3 samples.

How the data were processed

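The series holds ChIP-seq of dmrt11E tagged with enhanced green fluorescent protein in Drosophila melanogaster embryos of mixed sex at 2 to 10 h, with 1 group and 3 biological replicates whose numbers were taken from the labels. Per the labels, the factor carried a C-terminal fluorescent tag, the immunoprecipitation used an antibody against the tag, and chromatin was sheared by sonication to a size range of 200 to 800 bp. The labels number the biological replicates but name no separate collections beyond that, so spreads between replicates measure these 3 samples. The labels' age field holds a value that cannot be read as an embryo age, and the age was taken from the source name.

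Per the file headers, meaning the descriptions that came with each sample, peaks were called by the authors on each replicate and on the 3 replicates pooled, each against the same 1 control, on assembly dm6. The aligner, the peak caller and their settings are not given in the sources used here. Each deposited list gives per peak a position, a summit, a signal value (the authors' score, on a scale that differs between lists) and a q-value as −log10 q. The signal value deposited by the authors served to rank peaks and to compare promoter with other peaks within a list, and the −log10 q deposited by the authors served only to describe the lists. The 3 replicate lists and the pooled list hold 30000 peaks each, which is a fixed number and not a significance limit. The authors' optimal IDR set holds 6706 peaks, all of them in the pooled list and among its 6706 highest signal values. A comparison of IDR peaks with the 22192 pooled peaks that no IDR peak overlaps is therefore a comparison by signal within 1 list. Lists hold some overlapping or identical intervals: merging overlaps leaves 6504 regions in the IDR set, 25962 in the pooled list and 27106, 25984 and 26270 in replicates 1, 2 and 3. The lists say nothing of read depth, and precision is given by the number of peaks and the spread between replicates. No list of a control immunoprecipitation without the tag was analysed here.

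Summits were assigned to genes and classes with the Ensembl release 115 annotation (BDGP6.54) and sequence was taken from the RefSeq copy of the same assembly. Every peak end lies within its arm's length in that sequence, and only arms 2L, 2R, 3L, 3R, 4, X and Y were used. Transposable elements annotated as genes were left out, which leaves 18277 genes and 24111 distinct TSSs. Coordinates are printed counting from 1.

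The following choices were made before the data were examined: the tests, the alternatives, 25 gene lists, 15 motifs and the rule for named genes. N was set to the size of the IDR set, and the top N peaks of a replicate are its 6706 highest signal values. A peak was shared when it and its partner overlapped reciprocally by at least 50%, and chance came from 1000 circular shifts within each arm. A summit within 500 bp of an annotated TSS counted as promoter. Other classes followed in the order 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Shares carry exact 95% binomial intervals. Motifs and 7-mers were searched on both strands within 50 bp of summits and in windows of the same 101 bp width centred 500 bp to either side, with an exact McNemar test against 1 flank chosen by a seeded coin. The ratio used both flanks. The named 7-mers were learnt on 2L, 2R and 4 and tested on 3L, 3R and X. Gene lists were tested with Fisher's exact test, two-sided, among protein-coding genes with a pooled summit within 500 bp of a TSS. Peak signal by class used 100000 permutations. Families of tests were adjusted by Benjamini-Hochberg at a threshold of 0.05. The named genes are dmrt11E, dsx, dmrt93B and dmrt99B, the genes at the 15 IDR peaks of highest signal (a TSS within 500 bp, else the gene body, else the nearest TSS), and for each list the 3 members with the highest IDR promoter peak. Of these, 1 of the 15 peaks and 1 list member are not described in the text. Of the list symbols, 739 matched the annotation directly, through a synonym with a unique match or through a short table of older symbols, and 9 did not match and were left out.

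Alternatives changed the overlap that counts as shared, the number of top peaks, the TSS window (200 or 1000 bp), the class order, the expected arm shares, the motif window (25 or 100 bp), the background, the gene assignment and the covariates. They also restricted the IDR peaks to the 3353 of higher signal, to those supported by a top peak of every replicate, or to those supported by both replicates other than a left-out one. Merged regions, the comparison with other orders of a motif's letters, the base composition values, subsets at the target locus and the gene-body model with gene length were added after seeing the data. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9. The procedures were tested on simulated data with known answers, and 11 of 11 simulated quantities were recovered.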

Results

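Binding of dmrt11E, a transcription factor of the DM-domain family to which doublesex also belongs, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 2 to 10 h, male and female together. The embryos came from a transgenic line in which dmrt11E carried a green fluorescent protein at its C-terminus, and chromatin was recovered with an antibody against that tag. There was 1 group with 3 biological replicates and no other condition, so the comparisons were between replicates, between peak sets, and between peaks and the genome. The deposited peak lists of the replicates held 30000 peaks each, as did the list from the pooled replicates, and read depth was not given in the sources used here. A further list held the 6706 pooled peaks that passed an irreproducible discovery rate (IDR) threshold. These 6706 IDR peaks were the 6706 highest signal values of the pooled list. Signal values and q-values are the authors' own and were compared only within a list. The peaks with −log10 q of at least 2 numbered 9206 in replicate 1, 15075 in replicate 2, 10842 in replicate 3 and 11618 in the pooled list.

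The first question was how far the replicates shared their strongest sites. Of the 6706 highest-signal peaks per replicate, 62.6% ± 5.71 (SD over 3 pairs of replicates) were shared between a pair under a reciprocal overlap of 50%. Replicates 2 and 3 shared 68.3%, replicates 1 and 2 shared 62.7%, and replicates 1 and 3 shared 56.8%. Circular shifts of one list along each chromosome arm gave 1.24%, 1.24% and 1.18% for the pairs 1 and 2, 1 and 3, and 2 and 3. No shift out of 1000 reached the observed share (permutation p = 0.000999 for each pair, one-sided, the smallest that 1000 shifts can give). The shifts give the overlap of chance placement only. Agreement that comes from the shared control or from open chromatin was not measured. Across peaks shared by a pair, Spearman's rho of the signal value was 0.783 for replicates 2 and 3 over 14513 peaks, 0.730 for replicates 1 and 2 over 14559 peaks and 0.687 for replicates 1 and 3 over 13458 peaks. These are correlations across peaks, which are not independent replicates, and carry no test. Of the strongest sites, 82, 92 and 89 of the 100 highest IDR peaks were overlapped by a peak among the 100 highest of replicates 1, 2 and 3.

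Of the 6706 IDR peaks, 3139 were overlapped by a top peak in every replicate, which is 46.8% (exact 95% binomial interval 45.6 to 48.0%). The share per replicate was 63.7% in replicate 1, 75.9% in replicate 2 and 76.5% in replicate 3. With any overlap of 1 bp, 69.1% were found in every replicate, 1520 IDR peaks were overlapped in 2 replicates, 539 in 1 and 14 in none. Intervals cover counting error only.

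The gene of the tagged factor held IDR peaks. A fusion construct can add copies of this locus, and the labels do not say whether it did, so these peaks are given as a check. At dmrt11E (FBgn0030477, X, 13368191 to 13370472, plus strand, dm6), 3 IDR peaks had summits within the gene or 5000 bp of it. The strongest spanned 13368152 to 13368525, with its summit 154 bp downstream of the transcription start site (TSS). It had a pooled signal of 2210.7 and ranked 156 of the IDR peaks, and the overlapping peaks ranked 148, 137 and 206 in replicates 1, 2 and 3. A peak past the end of the gene, at 13373275 to 13373732, ranked 481 and lay within 500 bp of a TSS of CG1640, and an intronic peak at 13369504 to 13369907 ranked 3364. The intronic peak varied most between replicates, at ranks 1751, 2708 and 5813. Among the other DM-domain genes, doublesex (dsx, FBgn0000504, 3R), the switch of somatic sex differentiation, held 3 IDR peaks. The strongest, at 7962993 to 7963332, was 394 bp upstream of a TSS and ranked 1082, with ranks of 2112, 1960 and 622 in replicates 1, 2 and 3. The gene dmrt99B (FBgn0039683, 3R) also held 3 IDR peaks within 5000 bp, none within 500 bp of its TSS. The best of these lay in its 3' UTR at 29696441 to 29696684, with ranks of 1896 in the IDR set and 1925, 2023 and 1957 in the replicates. No IDR peak lay at dmrt93B (FBgn0038851, 3R), where the best of 4 pooled peaks ranked 17739.

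The 15 IDR peaks of highest signal included 11 within 500 bp of a TSS and were high in all 3 replicates. The highest, at the plexus gene px (FBgn0003175), spanned 22514063 to 22514532 on 2R, with its summit 205 bp upstream of a TSS and a pooled signal of 8311.9, and it ranked 1 in every replicate. The next, at CG14100 (FBgn0036889) on 3L, 19590381 to 19590845, ranked 2 in every replicate. A peak on 3R, 15229306 to 15229752, lay between Art3, an arginine methyltransferase gene, and mRpS10, which encodes a mitochondrial ribosomal protein, 129 and 128 bp upstream of their TSSs. It ranked 3 in the IDR set and 5, 5 and 3 in the replicates. At ph-p, a Polycomb group gene on X, the summit was 475 bp upstream of a TSS in the peak at 2137124 to 2137591, rank 4. CG1888 on 2R had the peak of rank 5, at 9546969 to 9547750. Rank 6, on 3L at 22878673 to 22879147, lay 192 bp upstream of the TSS of Ssl1, a TFIIH subunit gene, and 87 bp downstream of that of Chro, which encodes the chromatin protein Chromator. The peak of rank 8, on 2L at 480579 to 481317, was in an intron of ush, the gene of a cofactor of GATA factors, 4860 bp downstream of a TSS. Rank 9 lay between CHMP2B and Tcs5 on 3L, at 5139285 to 5139708. Ranks 11, 12 and 15 lay within 500 bp of a TSS of lncRNA:CR44339, Fkbp14 and CG13921. Ranks 10 and 13 were intergenic, with CG31668 and CG13321 as the nearest genes at 3760 and 4642 bp, and rank 14 was in an intron of CG11050. The lowest place that any of these 15 peaks took in a replicate was 29, at the site near CG13321 in replicate 1.

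IDR peaks lay at promoters more often than the weaker pooled peaks did as a whole, and almost never in coding sequence. Of the 6706 IDR summits, 2713 (40.5%, exact 95% interval 39.3 to 41.6%) lay within 500 bp of an annotated TSS. Promoters so defined took 13.3% of the placed genome, so the share was 3.04 times that of the genome. Among the 22192 pooled peaks that no IDR peak overlapped, the share was 26.3% (odds ratio 1.91, Fisher's exact test, two-sided, p = 2.6e-106). The top 6706 peaks of the replicates gave 41.1% ± 0.857 (SD, n = 3). The difference from the weaker peaks as a whole was therefore larger than the spread between replicates. In the pooled list the promoter share was 40.8% for signal ranks 6001 to 9000, which span the IDR limit, and 36.3% for ranks 9001 to 12000. It fell to 20.2% for ranks 27001 to 30000, so the difference came from the lower ranks and not from a step at the IDR limit. Coding exons held 9 IDR summits, which is 0.134% (exact 95% interval 0.0614 to 0.255%), against 6.11% of the weaker pooled peaks (odds ratio 0.0206, Fisher's exact test, adjusted p = 1.9e-142 over 7 classes) and 13.4% of the genome. The replicates gave 0.149% ± 0.0447 (SD, n = 3) for coding exons. In the pooled list, coding exons held 0.4% of the summits of ranks 6001 to 9000 and 11.3% of those of ranks 27001 to 30000. The 3' UTRs held 0.880% of IDR summits against 3.64% of weaker peaks (Fisher's exact test, adjusted p = 1.3e-38), and the 5' UTRs outside promoters held 0.418% against 1.30% (adjusted p = 4.0e-11).

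Introns outside promoters held 36.1% of IDR summits, below the 41.2% of weaker peaks (adjusted p = 1.1e-13) and the 39.2% of the genome (exact binomial test, adjusted p = 2.4e-07). Intergenic sequence held 21.1%, below its 28.2% of the genome (exact binomial test, adjusted p = 1.1e-39), and the difference from the 20.5% of weaker peaks did not pass (Fisher's exact test, adjusted p = 0.34). Other exons, mostly of noncoding genes, held 0.954% and passed neither exact test (adjusted p = 0.22 against the genome and 0.63 against weaker peaks). The directions for introns and intergenic sequence against the genome rested on the promoter class. With that class left out, 45.1% of IDR summits were intergenic against 31.4% of the genome, and 45.3% were intronic against 42.3%. The median distance from an IDR summit to the nearest TSS was 1006.5 bp (quartiles 166 and 4159 bp), against 1653.5 bp for the weaker peaks.

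**Figure D1:**
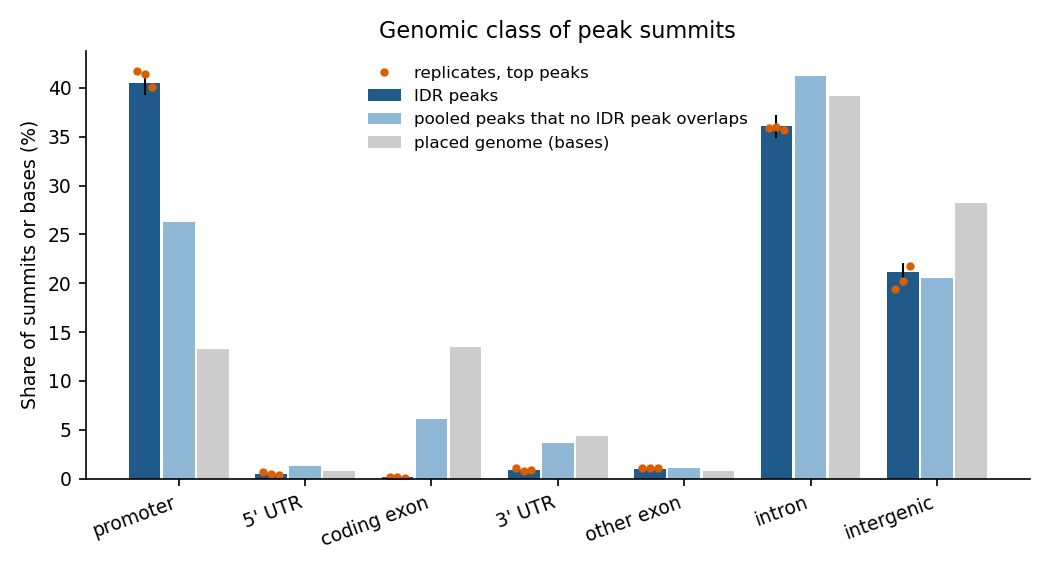
Share of summits (%, vertical axis) in each of 7 genomic classes for IDR peaks (dark bars, with exact 95% binomial intervals), for pooled peaks that no IDR peak overlaps (light bars) and for the bases of the placed genome (grey bars). Points are the top 6706 peaks of each of the 3 replicates, which lie at 40.1 to 41.7% for promoters, and the coding exon bar of the IDR peaks is at 0.134%.

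IDR peaks were spread over all large chromosome arms at similar density, from 43.9 peaks per Mb on 2R to 53.8 peaks per Mb on 3L. The X held 17.9% of IDR peaks against 17.1% of the arm length (exact binomial test, adjusted p = 0.12 over 7 arms), and 3R held 23.5% against 23.3% (adjusted p = 0.69). By the same exact test, arms 2L (18.8% against 17.1%, adjusted p = 0.00043) and 3L (22.6% against 20.4%, adjusted p = 6.8e-05) held more than their length, and 2R (16.5% against 18.4%, adjusted p = 0.00019) held less. Chromosome 4 held 47 peaks, or 0.701% against 0.980% of the length (exact binomial test, adjusted p = 0.026). No IDR peak lay on the Y, which makes up 2.67% of the length (exact binomial test, adjusted p = 2.6e-78), and none of the 30000 pooled peaks did either. In embryos of mixed sex the X, the Y and the autosomes differ in copy number, which arm length leaves out. The tests of X and Y therefore cannot separate fewer sites from lower detection. Set against the weaker pooled peaks instead of arm length, 2 arms differed: 2R held less (odds ratio 0.858, Fisher's exact test, adjusted p = 0.00013) and 3R held more (odds ratio 1.16, adjusted p = 4.5e-05). The 5 arms that passed against length fell to 3 without replicate 2 and to 2 without replicate 3. These settings keep 3514 and 3726 of the IDR peaks, so the lost calls cannot be read as dependence on a replicate.

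Among gene groups, the promoters of ribosomal protein genes stood out. Of the 13968 protein-coding genes, 7211 had a pooled summit within 500 bp of a TSS and formed the background, and 3323 of these (46.1%) had an IDR summit there. A gene called bound below is one with an IDR summit there or, where stated, in its gene body. No control without the tag was analysed here, so binding of the factor cannot be told apart from recovery of open chromatin at these genes. Of the 86 ribosomal protein genes in the background, 73 (84.9%, exact 95% interval 75.5 to 91.7%) had an IDR promoter summit (odds ratio 6.70, Fisher's exact test, two-sided, adjusted p = 2.0e-12 over 25 lists). The replicates gave 85.7% ± 2.42 (SD, n = 3). RpS27 had the highest peak of the list, at rank 377, and RpL34b had one at rank 524. The median rank of the 73 was 2395, and 8 had a peak among the 1000 highest and 53 among the 3353 of higher signal. The share was 60.5% without replicate 1, 54.7% without replicate 2 and 54.7% without replicate 3, settings that keep 4164, 3514 and 3726 of the IDR peaks. The list passed the threshold in each (Fisher's exact test, adjusted p = 3.1e-07, 5.5e-07 and 1.4e-06), and over all alternatives the adjusted p lay between 6.4e-28 and 1.4e-06. Odorant and gustatory receptor genes, which act in sensory neurons, had an IDR promoter summit at 0 of 10 members (Fisher's exact test, adjusted p = 0.031). This call ended without replicate 1, 2 or 3, where fewer IDR peaks were kept (Fisher's exact test, adjusted p = 0.31, 0.49 and 0.36).

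No other list passed the threshold, including those of the tissues in which developmental regulators act. Mesoderm and muscle regulators had 7 of 30 members bound (23.3%, Fisher's exact test, p = 0.016, adjusted p = 0.088). Those bound included strong sites at the FGF receptor adaptor gene stumps (rank 78), the T-box gene org-1 (rank 157) and the cardiac homeobox gene tin (rank 324). When any IDR summit in the gene body or 1000 bp of it was counted, 27 of 34 members (79.4%) were bound, above the 53.1% of other genes (Fisher's exact test, adjusted p = 0.024). Dpp and EGFR signalling genes had 5 of 19 promoters bound (26.3%, Fisher's exact test, adjusted p = 0.38), with aos (rank 288), spi (rank 322) and Ras85D (rank 2883) highest, and 20 of 23 (87.0%, adjusted p = 0.014) by gene body. These last calls did not pass when a logistic model with gene length and number of TSSs replaced the exact test (adjusted p = 0.28 for both lists), although the odds ratios stayed above 1, at 2.21 for mesoderm and muscle regulators (3.41 before) and 3.75 for Dpp and EGFR signalling genes (5.88 before). The pair-rule genes had 0 of 7 members bound (Fisher's exact test, adjusted p = 0.088), hemocyte and fat body genes 1 of 11 (Adh, rank 4723, adjusted p = 0.088) and tracheal genes 1 of 10 (adjusted p = 0.11), although that gene, the tracheal regulator trh, had the peak of rank 388.

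The Notch pathway and E(spl) complex list had 11 of 23 members bound, close to the background share, and held strong sites: E(spl)m7-HLH ranked 34, numb ranked 36 and E(spl)mdelta-HLH ranked 38. Neuroblast and proneural genes had 5 of 17 bound, led by grh (rank 1068), mira (rank 1838) and vnd (rank 2390). Neuronal differentiation genes had 2 of 4, of which elav, an RNA-binding protein gene of neurons, ranked 162 and fne 5523. Glial genes had 3 of 12, led by nkd (rank 606), moody (rank 1284) and wrapper (rank 3752). The replicate peaks matched to the nkd peak ranked 20178 in replicate 1, 499 in replicate 2 and 7475 in replicate 3. Matched ranks ranged widely for other named peaks too, such as those of fne (17843, 5261 and 4027), Tm1 (12377, 1263 and 719) and WASp (3398, 17365 and 4260). The matched peak was the one with the largest overlap, and the replicate lists hold overlapping peaks, so a weaker neighbour may have been ranked. These ranges therefore cannot be read as variation between replicates. Sex determination genes had 7 of 15 bound, led by the corepressor gene gro (rank 472), dsx and Sxl (rank 1441), and germline and gonad genes 7 of 17, led by Sox100B (rank 342), piwi (rank 679) and gcl (rank 1344). The DM-domain list had 2 of 2 measured members bound, dmrt11E, to whose locus the fusion construct may have added copies, and dsx. Muscle structural genes had 5 of 11, led by sls (rank 492), Tm1 (rank 991) and Act87E (rank 1024), and myoblast fusion genes 7 of 14, led by mbc (rank 1139), WASp (rank 3282) and Vrp1 (rank 3302). The list of Hox genes, in which bcd was counted, had 4 of 7, led by Dfd (rank 1454), bcd (rank 2614) and lab (rank 3294). Segment polarity and Wnt/Hh genes had 5 of 14, led by nkd, Wnt6 (rank 1476) and smo (rank 4437).

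Gap and terminal genes had 1 of 6 bound (oc, rank 6594), epidermal and cuticle genes 4 of 12 (grh, shg at rank 3114 and sdt at rank 3299 highest) and endoderm and midgut genes 3 of 8 (fkh at rank 3174, lab, and Ance at rank 3592). Genes of zygotic genome activation and pioneer factors had 5 of 8, led by grh, bcd and the CBP gene nej (rank 2996). Proteasome genes had 12 of 30, led by Rpn3 (rank 1189), Rpn5 (rank 1687) and Rpn11 (rank 1963), and heat shock genes 4 of 9, led by Hsp27 (rank 323), Hsp83 (rank 1249) and Hsp60A (rank 4488). Histone genes, of which 2 of 111 had a pooled promoter summit, had 0 of 2. The adjusted p (Fisher's exact test) of the lists named without one lay between 0.501 and 1, and these lists have few measured members.

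**Figure D2:**
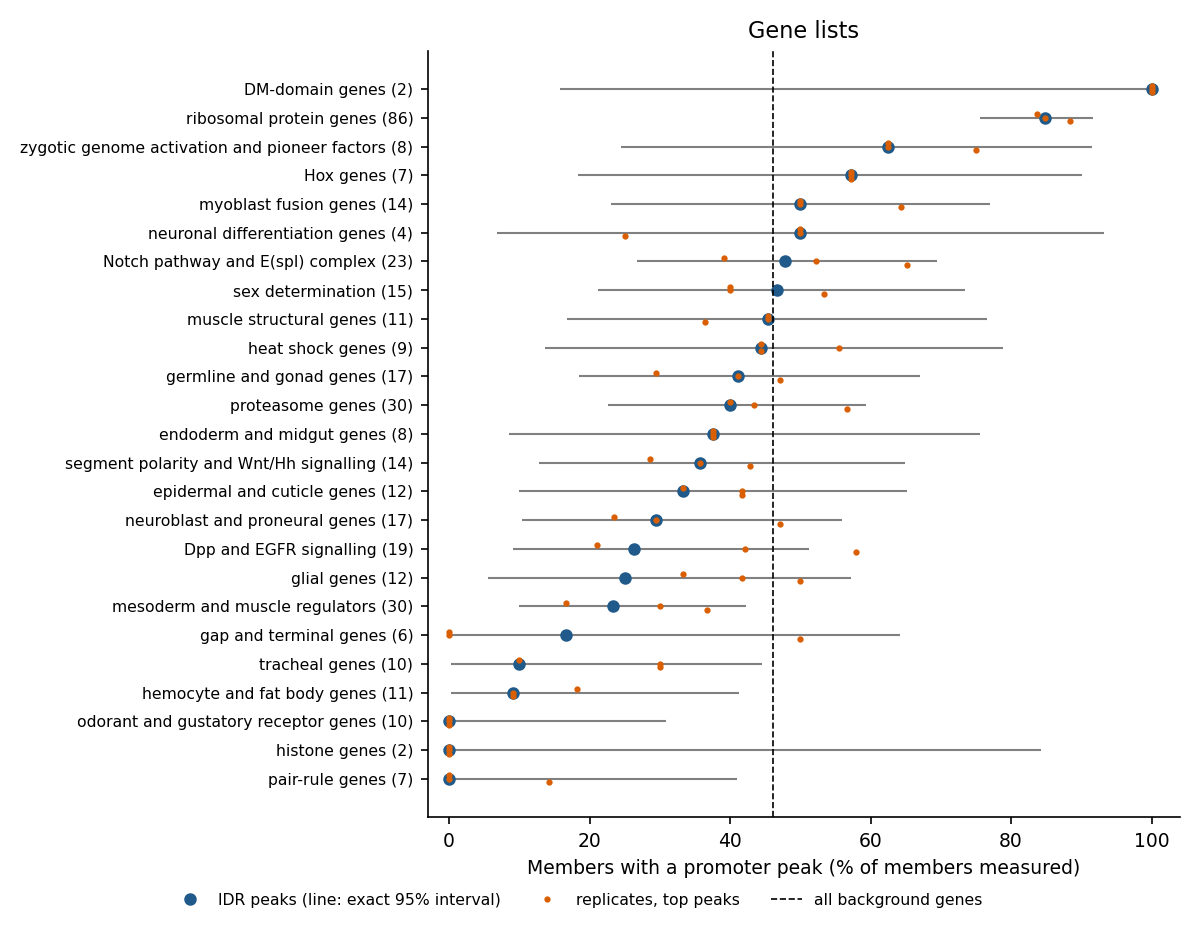
Share of each list's measured members (number in brackets) with a promoter peak (%, horizontal axis), for IDR peaks (large points, with exact 95% binomial intervals) and for the top 6706 peaks of each of the 3 replicates (small points). The dashed line is the 46.1% of all background genes, and ribosomal protein genes lie at 84.9%.

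The DNA motif bound by the family was rare at the summits and only slightly above its level in the flanks. The core ACAATGT, shared by doublesex and vertebrate DMRT sites, lay within 50 bp of 131 of 6706 IDR summits (1.95%, exact 95% interval 1.64 to 2.31%) and in 1.36% of windows 500 bp to either side. The ratio was 1.43 (exact McNemar test, two-sided, p = 0.023, adjusted p = 0.039 over 15 motifs), and the replicates gave 1.47 ± 0.110 (SD, n = 3). The excess was found at non-promoter peaks (2.20% against 1.21%, exact McNemar test, p = 0.0007) and not at promoter peaks (1.58% in both, p = 0.74), a difference that was not itself tested. The call ended for the doublesex consensus RNNACWAWGTNNY (ratio 1.51, exact McNemar test, p = 0.087), against weaker pooled summits (1.14, Fisher's exact test, p = 0.19) and without replicate 1 (exact McNemar test, p = 0.23), where the ratio, 1.5 over 4164 peaks, was not lower. The test used 1 flank per peak, drawn by coin for each set of peaks. The smaller set supported by every replicate passed at a ratio of 1.53 (exact McNemar test, p = 0.049). The call lost without replicate 1 therefore cannot be read as dependence on that replicate. Other orders of the same 7 letters had a median ratio of 1.59, and 36.5% of them lay below the ratio of the core.

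Of the 15 motifs, 5 were more frequent at summits than in flanks and 4 less frequent. The DREF site TATCGATA, a word of housekeeping promoters, had the highest ratio, 5.0 (1.19% against 0.239%, exact McNemar test, adjusted p = 3.4e-11), with 5.77 ± 0.894 in the replicates (SD, n = 3). The excess over flanks lay at promoters: with promoter peaks left out the ratio was 0.857 (exact McNemar test, adjusted p = 0.91), and against weaker pooled summits it was 1.07 (Fisher's exact test, adjusted p = 0.64). The homeodomain core TAATTA was found at 11.8% of summits against 6.01% of flanks (ratio 1.97, exact McNemar test, adjusted p = 7.0e-29), the Fox word TGTTTAC at 3.79% against 1.97% (1.92, adjusted p = 1.1e-09) and the Caudal word TTTATTG at 5.56% against 3.73% (1.49, adjusted p = 5.8e-05). The Fox call ended without replicate 2 (1.39, exact McNemar test, adjusted p = 0.061) and among peaks supported by every replicate (1.39, adjusted p = 0.29). Divided by the median of the other orders of the same letters, the homeodomain word was at 0.747, below the middle 90% of its 13 other orders. The Caudal (0.852, turned below 1) and Fox (1.40) words lay within the middle 90% of theirs. The GAGA factor word GAGAGAG was less frequent (0.626% against 2.30%, ratio 0.273, exact McNemar test, adjusted p = 3.0e-14), as were the E-boxes CACATG (0.624, adjusted p = 2.8e-09) and CAGCTG (0.508, adjusted p = 3.1e-09) and the Su(H) word TGGGAA (0.710, adjusted p = 8.3e-06). Against other orders of the same letters none of these 4 lay outside the middle 90%: the GAGA word was at 0.704 and CACATG at 0.825 times the median order, and CAGCTG (1.08) and the Su(H) word (1.01) turned above 1. The Zelda word CAGGTAG missed the threshold (0.589, exact McNemar test, adjusted p = 0.071), but passed it in the replicate-supported sets, at 0.388, 0.296 and 0.393 without replicates 1, 2 and 3. Other orders of its letters had a median ratio of 0.537, so against them the Zelda word turned to 1.10. GATA (1.26), Grainyhead (0.417), Mef2 (1.67), Sox (1.52) and Pangolin (0.996) words did not pass, with adjusted p between 0.095 and 1 (exact McNemar test). Sox passed among peaks supported by every replicate (1.66, adjusted p = 0.0067), without replicate 2 (1.58, adjusted p = 0.033) and with promoter peaks left out (1.48, adjusted p = 0.013), all by the exact McNemar test. GATA passed with promoter peaks left out (1.31, exact McNemar test, adjusted p = 0.022). Other settings in which these 5 or the Zelda word passed are windows of 100 bp (Zelda, Grainyhead, Mef2 and Sox), merged regions (GATA and Sox), and, for Zelda, the IDR peaks of higher signal and those supported by every replicate.

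**Figure D3:**
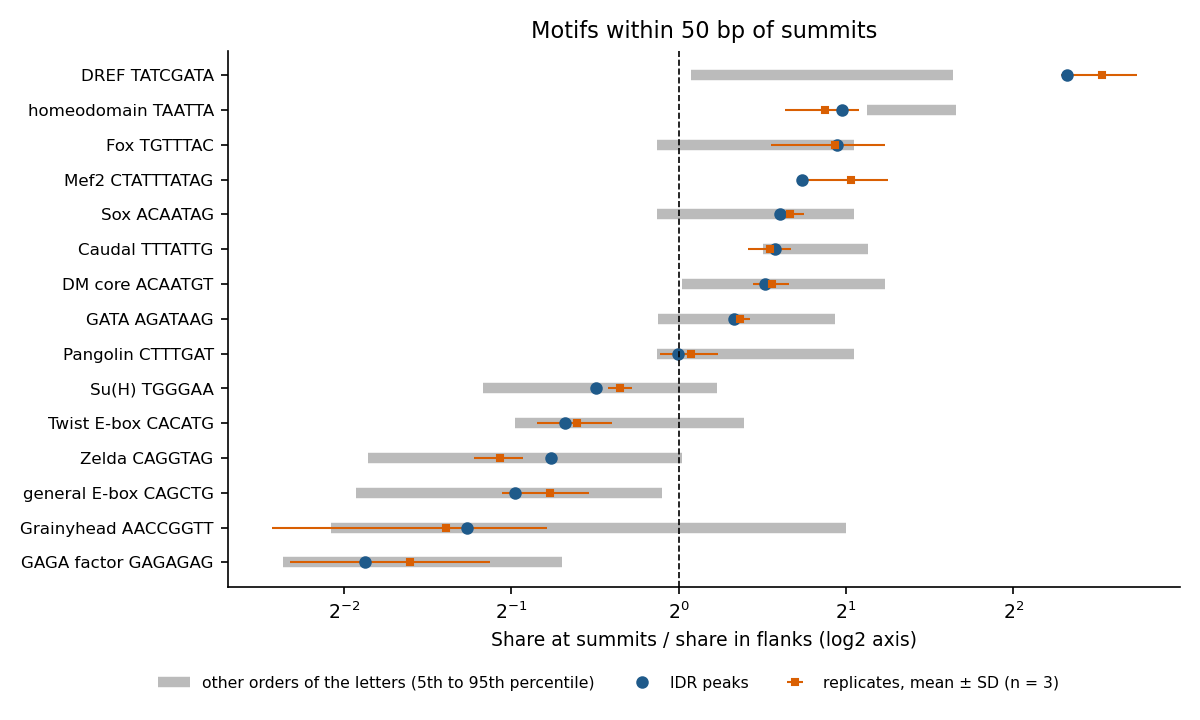
Share of peaks with each motif within 50 bp of the summit divided by the share in the flanks (horizontal log2 axis) for 15 motifs fixed beforehand. Round points are the 6706 IDR peaks, squares with bars the mean ± SD of the 3 replicates, and grey bars the middle 90% of the other orders of each motif's letters, which were not computed for Mef2; the DM core, at 1.43, lies inside its grey bar.

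The words that set summits apart from their flanks were rich in A and T. Of 8192 7-mers with strands merged, 1596 were more frequent at summits and 3860 less frequent (exact binomial test, adjusted p under 0.05), and 87.3% of those more frequent held 5 or more A or T, against 22.7% of all 7-mers. The 10 words with the lowest p on arms 2L, 2R and 4 were TTTAAAA, TAAATAA, AAATATA, ATATTTA, AAAATAT, AAATATT, TAAAATA, TTAAAAA, ATAATAT and TATTTAA. All 10 passed again on 3L, 3R and X, where TTTAAAA had a ratio of 3.63 (exact binomial test, adjusted p = 2.8e-92) and TAAATAA, the lowest of the 10, 2.73 (adjusted p = 2.3e-60). All 10 hold only A and T, and on all arms together each of the 64 7-mers of that kind was more frequent at summits. The second pass therefore repeats the AT content of summits and does not single out these words. Of bases within 50 bp of IDR summits, 68.8% ± 0.107 (SE over 6706 peaks) were A or T, against 56.2% in the flanks. The weaker pooled peaks had 60.1% at the summit and the genome 57.9%. Replicates gave 68.0% ± 1.92 (SD, n = 3), with 65.9% in replicate 1, 68.2% in replicate 2 and 69.7% in replicate 3.

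**Figure D4:**
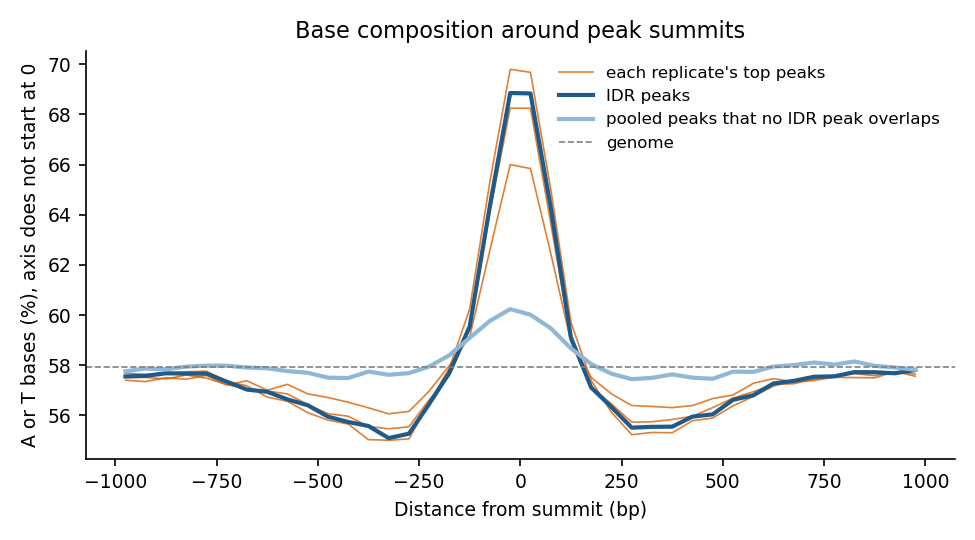
Share of A or T bases (%, vertical axis, which does not start at 0) in bins of 50 bp by distance from the summit (bp, horizontal axis) for IDR peaks, weaker pooled peaks and the top 6706 peaks of each replicate. The IDR line peaks at 68.9% beside the summit and falls to 55.1% at 300 to 350 bp before it, below the genome at 57.9% (dashed line).

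Promoter peaks and other peaks had similar signal. The median signal was 328.8 for the 2713 IDR promoter peaks and 318.2 for the 3993 others, a difference of 10.6 (permutation test with 100000 resamples, two-sided, p = 0.17). Among the 3353 IDR peaks of higher signal the difference was 56.8 (permutation p = 0.0001), and with promoters taken as 1000 bp from a TSS it was 15.45 (permutation p = 0.039).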

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

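No paired analysis was possible because there is 1 group. The comparison with other letter orders, the merged regions and the gene-body model with gene length were chosen after seeing the data. Of 146 values of the main results under an alternative, 103 kept their direction and side of the threshold, or for values with no test stayed within the replicate SD and for counts within 1.5 times, among them the promoter share (28.3 to 49.9%), the coding exon share, both counts of 7-mers, the ribosomal protein call and the peaks at dmrt11E (2 or 3) under all their alternatives. Of 463 values of single classes, arms, motifs and lists, 421 did, 16 lost and 18 gained a call, and 8 reversed. Where a cause is not named, the cause was not tested.

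Replicate overlap was 78.5% with any overlap of 1 bp, 72.6% with summits within 100 bp, 79.5% for the 1000 highest peaks and 49.7% for all deposited peaks (56.8 to 68.3% without each replicate). Rank agreement was 0.793 with summits within 100 bp and 0.850 among the top peaks of both lists (0.687 to 0.783 without each replicate). IDR peaks found in every replicate were 69.1% with any overlap of 1 bp, 63.2% with summits within 100 bp, 71.0% against all deposited peaks and 72.0% of the higher-signal IDR peaks (52.4 to 62.1% without each replicate, which asks for fewer lists). Without a promoter class, intronic (45.3%), intergenic (45.1%) and 5' UTR (5.59%) summits reversed against the genome, since promoter bases then join those classes. Arms past the threshold were 2 against weaker pooled peaks and 2 to 5 without each replicate, where fewer IDR peaks were kept.

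The DM core ratio was 1.51 for the doublesex consensus, 1.14 against weaker pooled summits (1.47 to 1.59 without each replicate) and reversed to 0.900 when divided by the median of the other letter orders. Divided in this way, 2 of the motifs lay outside the middle 90% of the other orders (DREF above, the homeodomain word below), and the homeodomain (0.747), Caudal (0.852), general E-box (1.08) and Su(H) (1.01) words reversed. DREF reversed to 0.857 with promoter peaks left out.

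The lists past the threshold were 1 with a TSS window of 1000 bp, 1 among the higher-signal IDR peaks, 1 among peaks supported by every replicate, 1 without each replicate (1 to 1), 1 with gene length and number of TSSs in the model, and 1 by gene body in that model. The odorant and gustatory receptor share was 12.5% with a TSS window of 1000 bp, 26.9% by gene body and 26.9% by gene body in the model, and stayed 0% but lost its call among the higher-signal peaks, among peaks supported by every replicate and without each replicate (0 to 0%), where fewer peaks were kept. The model without gene body could not be fitted to its 0 of 10. Mesoderm and muscle regulators (79.4%) and Dpp and EGFR signalling genes (87.0%) reversed by gene body. The signal difference between promoter and other peaks passed with a TSS window of 1000 bp (15.45) and among higher-signal peaks (56.8), and ranged from 1.48 to 23.9 without each replicate.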

Other observations

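The tests in this part, on opposite strands, further families, words, base composition and letter orders, were chosen after the main results were seen, although the outcomes that would decide the search for repeat copies and the letter orders were fixed before their own results. Of the 11 promoter peaks among the 15 highest, 4 had summits near TSSs on opposite strands, and such peaks were common among the others. Of the other 2702 IDR promoter peaks, 1013 (37.5%, exact 95% interval 35.7 to 39.3%) lay within 500 bp of TSSs of protein-coding genes on both strands, against 15.2% of 5827 weaker pooled promoter peaks (odds ratio 3.36, Fisher's exact test, two-sided, p = 8.1e-112). The replicates gave 36.0% ± 2.57 (SD, n = 3). Among 6 further gene families, mitochondrial ribosomal protein genes had 38 of 61 promoters bound (62.3%, Fisher's exact test, p = 0.014, adjusted p = 0.082), with mRpS10, mRpS23 and mRpL41 at ranks 3, 39 and 66. Aminoacyl-tRNA synthetase genes had 15 of 22 (Fisher's exact test, adjusted p = 0.16), mediator complex genes 13 of 24 (adjusted p = 0.65), translation initiation factor genes 15 of 34 (adjusted p = 0.86), cytochrome P450 genes 5 of 17 (adjusted p = 0.34) and Cpr cuticle protein genes 0 of 4 (adjusted p = 0.26).

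Some words within 100 bp of the summit differed in frequency between promoter and non-promoter peaks. CACTGAGA lay at 244 of 3993 non-promoter IDR peaks (6.11%, exact 95% interval 5.39 to 6.90%) against 0.513% in the flanks, a ratio of 11.9 (exact McNemar test, p = 1.3e-49), and at 1.70% of promoter peaks against 0.461% in their flanks, a ratio of 3.68 (exact McNemar test, p = 3.3e-06). The difference between the classes passed (Fisher's exact test, p = 3.4e-20). The words in this paragraph were chosen after the same peaks had been examined. The tests against flanks, the ratios by arm and the tests between the classes are therefore not independent support. CACTGAGA lay at 1.66% of the weaker non-promoter peaks, and the replicates gave 5.75% ± 0.578 (SD, n = 3). The ratio was above 1 on each large arm, from 6.0 on X to 19.3 on 3R. Most copies sat beside the summit and not on it: 102 lay 80 to 100 bp away and 8 within 20 bp. TATCGATA was found at 6.86% of promoter peaks and 0.426% of the others (Fisher's exact test, p = 9.6e-55), and the core promoter word GGTCACACT at 2.58% and 0.175% (p = 1.3e-20). At weaker promoter peaks TATCGATA was found at 5.97% and GGTCACACT, more often than at IDR promoter peaks, at 4.08%.

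For the words beside non-promoter summits, the tables argue against base composition as the whole cause. The 10 words were learnt on 2L, 2R and 4. On 3L, 3R and X all 10 again had a higher summit to flank ratio than words of the same letters. CACTGAG had the highest, at 7.0 times the ratio of those words (exact binomial test, adjusted p = 7.6e-62). Most of the 10 words hold CACTG on 1 strand and can lie at the same sites, so they are not 10 separate tests. CACTGAGA itself was first noticed on all arms, so the second set of arms is not an independent test of it. GAGAGAA, also among the 10, lay within 100 bp of 171 non-promoter summits on 3L, 3R and X, against a flank mean of 100. The similar GAGA factor word GAGAGAG was less frequent than in flanks within 50 bp of all IDR summits. The tables also argue against closely similar copies of a single repeated element, since 0% of the 273 CACTGAGA sites shared a stretch of 24 bp with another site over 1 kb away. Copies that have diverged, or an element shorter than 24 bp, would be missed by this search and stay open. What brings these words to the sites stays open. No biological explanation was tested, as the design has 1 group.

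The AT-rich summits may come from the chromatin recovered, from the assay or from the factor. A position at promoters was not the whole cause, because non-promoter summits were 11.6 points above their flanks. A preference of the assay for AT-rich fragments stays open: the AT content 200 to 350 bp from non-promoter summits differed by -4.79 points from that of introns and intergenic sequence (59.9%), but a fragment of 200 bp over the summit does not reach that far. Recovery of open chromatin without the tagged factor cannot be told apart from binding of the factor, since the DM core lay at 1.95% of summits and no control without the tag was analysed here.

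The small excess of the DM core over the flanks is consistent with base composition alone. Its ratio stood at the 36.5 percentile of 419 other orders of its letters, and at non-promoter peaks, where it was 1.81, at the 68.7 percentile, so these windows gave no sign of the core beyond their letters. What stays open is binding to other forms of the motif, which was not tested beyond the doublesex consensus.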
